A study of Mus musculus with 92 samples.

How the data were processed

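Livers of HET3 mice were profiled by RNA sequencing. Per the labels' protocols, tissue was snap frozen, RNA quality was assayed on a chip, and stranded libraries were prepared with selection of polyadenylated RNA. Libraries were pooled over 2 lanes and the lanes of a sample were merged before expression was estimated. The submitters' processing notes name edgeR, limma and R 3.4.3 and the genome build GRCm38.p5, with no roles. The aligner and the gene annotation are not given in the sources used here. Samples were grouped by the sex, diet and age at killing in their labels, which gave 92 libraries in 12 groups.

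A gene table holds estimated counts per gene, not normalized, as the authors deposited them. A table for each sex holds the authors' comparisons: log2 fold changes, p-values and Benjamini-Hochberg adjusted p-values, together with a deposited F statistic (a score over all comparisons of a gene). Which libraries, which filter and which model made these tables is not given in the sources used here. Each is called the authors' deposited table below. The female table lists 17192 genes, the male one 17757, and 17023 are in both. Positive fold changes mean higher on the restricted diet or at the older age.

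The gene table was found to be misaligned. Of its 51912 lines, 17275 are filled under all 47 female columns, and the other 34637 hold 47 cells each. In the upper lines, fold changes computed from the female columns correlated across genes with the deposited female fold changes at r = 0.91 to 0.95 over the 4 diet comparisons. For the male columns r lay between -0.01 and 0.01. The line of Alb, the main plasma protein made by liver, had a median estimated count of 1905880 under the female columns and 75 under the male ones. Counts were therefore used only for the 47 female libraries and the 17275 upper lines. Results for males, and for genes outside those lines, come from the authors' deposited table of each sex. The fit of all 92 libraries that was planned could not be made. The differences between the 2 restricted diets in males, their average over both sexes and ages, and the differences between the sexes among controls were not analysed here. Of the 17275 identifiers, 17251 matched GENCODE M21, an annotation of GRCm38, which gave gene symbols and positions.

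Estimated counts of the female libraries were rounded to whole numbers. They were filtered by expression (filterByExpr on the 6 female groups), scaled by TMM and fitted with edgeR's quasi-likelihood test with a mean per group in a single fit, under R 4.3.3 with edgeR 4.0.16. The fit covered 12623 genes. Benjamini-Hochberg adjustment ran over all genes tested, and a gene was called changed at an adjusted p under 0.05. Fold changes from counts are fitted log2 fold changes, with standard errors (SE) recovered from the fold change and the quasi-likelihood F. Levels are CPM, counts scaled to a library total of 1e+06, as mean ± SD. On simulated counts with 200 changed genes, the fit for Low Isoleucine against Control at 24 months recovered 41.8%, 89.6% and 95.5% of genes changed by 0.5, 1 and 2 log2 units, with 3 false calls among 12557 genes. For Low Amino Acid against Control at 6 months the shares were 44.8%, 79.1% and 100%, with 9 false calls among 12566 genes. These simulations drew each gene on its own, with a spread pooled over all groups. Aged female controls varied more than any other female group, so the simulated values do not show the false calls in comparisons with them.

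Averages over the 4 strata of sex and age, and differences between sexes or ages, were computed from the authors' deposited log2 fold changes and p-values. A t statistic and its standard error were recovered from each p-value, with 39.6 degrees of freedom for females and 36.3 for males as the deposited F statistics give them. Sums and differences of the independent contrasts were then tested on 17023 genes (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). In simulated data this recovered 193 of 200 changed genes in the average, with 0 false calls among 12000 genes. Each gene was drawn there on its own, with the same spread in all groups. These tests rest on the authors' unstated model and on libraries that are not all known. In the male table the median ratio of standard errors, Low Amino Acid over Low Isoleucine at 6 months, was 0.88. Both groups hold 7 libraries, and equal groups would give near-equal errors, so some male libraries may be left out. A fit of all 45 male libraries with a mean per group would also leave more than 36.3 degrees of freedom. Which male libraries entered is unknown. When the deposited female fold changes were matched to the counts, 5 female libraries were found not to enter that table: replicate 3 of the 6-month Low Isoleucine group, replicates 2 and 4 of the 24-month Low Amino Acid group, and replicates 2 and 5 of the 24-month Low Isoleucine group.

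The groups, contrasts, gene lists, thresholds and 7 alternative settings for the counts were fixed before the data were examined. 5 further settings for the counts, and the leaving out of each of the 47 libraries in turn, were added after seeing the data, as was every use of the deposited tables in place of male counts. Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom (limma 3.58.1) with and without sample quality weights, limma-voom with the shared title number as a block, no filter on low counts, and fits on fewer libraries. The setting without a library whose sex-linked genes go against its label was planned on Xist and 4 genes of the Y chromosome, and was run on Kdm5d alone, the only one of these in the upper lines. Genes are named by a rule fixed in the same way. It takes 8 genes whatever their values, and the 10 largest changes in each direction that passed in an average, with the same sign in all 4 strata, or in an age comparison of controls. It takes the 5 largest in each direction that passed in any other comparison, and up to 4 members with the smallest p from each list described. A mean CPM of at least 1 in the female libraries was required of genes with counts. The rule asked it of every gene, but it could not be applied to genes without counts, nor was it applied in the male table, so genes of low level can be named there. Gene models without a given name were left out unless stated. Of 37 gene lists, 35 could be tested in the female counts and 36 in the male table. They were tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and, for the counts, with fry. For the deposited tables the estimated correlation came from the female counts. In the 14 comparisons within a sex, camera at the preset correlation called between 4 and 26 lists, and 0 with an estimated correlation. fry called 19 lists for age in females, 2 for Low Isoleucine in 24-month females and 0 in the other 7 comparisons of counts. List counts below are single-gene calls.

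Numbers in the sample titles are shared by some libraries (42 libraries, 19 numbers), always within a group, and their meaning is not given in the sources used here. Genes that share reads with near-identical copies (Mup genes, clustered histone genes, Cyp2 and Cyp4a families, Saa genes, Olfr genes) are uncertain, since the counting could split such reads. Fold changes of genes near 0 in a group depend on the prior count. P-values measure the spread between animals of a group as labelled. No batch is given in the labels.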

Results

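RNA from the livers of fasted HET3 mice, a genetically heterogeneous cross of inbred strains, was sequenced in both sexes at 2 ages on 3 diets: Control, Low Amino Acid (less of all amino acids) and Low Isoleucine (less of that essential branched-chain amino acid alone). Animals were killed at 6 or 24 months per the labels, and the series description instead gives 13 weeks on diet for both ages, so age here is the labelled age and time on diet is uncertain. By the labels diets began at 9 weeks in the younger animals and at 6 months in the older ones, so diet differences between the ages cannot be told apart from starting age or time on diet. The 92 libraries, 47 labelled female and 45 labelled male, fell into 12 groups. There were 7 animals in each of 4 groups (24-month females and 6-month males on Low Amino Acid, 6-month males on Low Isoleucine, 24-month male controls) and 8 in each of the others. Totals per female library, over the genes whose lines could be assigned, had a median of 22.4 M counts (M, counts in units of 1e+06) and a highest value of 27.6 M. The lowest was 7.82 M, in replicate 5 of the 24-month Low Isoleucine group, and the next lowest was 13.8 M. Depth of the male libraries is unknown here, because their columns could not be assigned to genes.

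Aged female controls varied more than any other female group. The median SD of log2 CPM within a group was 0.365 in 24-month controls, against 0.270 in 6-month controls, 0.272 and 0.289 in the 24-month Low Amino Acid and Low Isoleucine groups, and 0.215 and 0.291 in the 6-month ones (12623 genes). The first principal component held 27.7% of the variance, the second 7.03%. By the median Spearman correlation with their own group, 12 of the 47 female libraries stood apart (below 0.970, with a median over libraries of 0.984). These were all 8 aged controls, 2 libraries on Low Amino Acid at 24 months and 2 on Low Isoleucine at 24 months. Saa2, an acute phase protein, stood at 1210 ± 1953 CPM in aged controls (SD, n = 8) and 6.35 ± 3.94 CPM in young controls (SD, n = 8). The aged controls differed here among themselves: the mean log2 CPM of the acute phase list was 10.9 in replicates 1 and 5, and 7.88 and 7.92 in replicates 2 and 6, within the 7.67 to 8.26 of young controls.

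**Figure D1:**
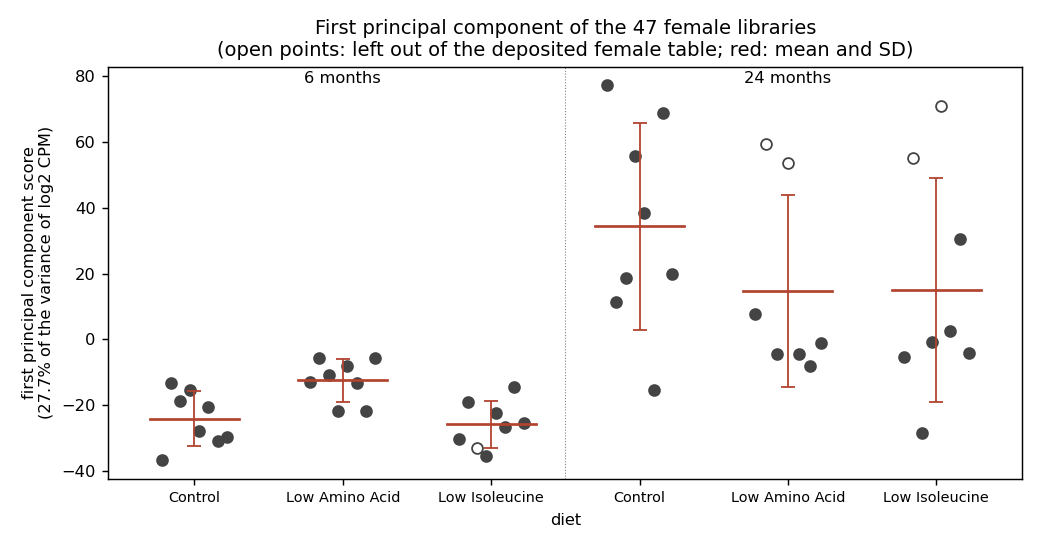
First principal component score of log2 CPM for each of the 47 female libraries by age and diet, with red lines for the mean and SD of a group and open points for the 5 libraries that the deposited female table leaves out. Scores were spread more widely in the 24-month groups than in the 6-month ones.

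8 genes were followed whatever their values. In female libraries Fgf21 (chromosome 7, 45613886 to 45615490), a hormone secreted by liver on low protein intake, stood at 16.4 ± 8.03 CPM in 6-month controls (SD, n = 8), 16.1 ± 7.86 on Low Amino Acid (SD, n = 8) and 17.3 ± 8.70 on Low Isoleucine (SD, n = 8), and it passed in none of the diet comparisons from female counts. Srebf1 (chromosome 11, 60199089 to 60222581), a driver of fatty acid synthesis, was at 204 ± 55.5 CPM in 24-month controls (SD, n = 8) and 112.7 ± 30.5 on Low Isoleucine (SD, n = 8). Fasn (chromosome 11, 120805846 to 120824547), the fatty acid synthase, stood at 309 ± 89.4 and 171 ± 57.7 CPM in those groups (SD, n = 8 each). Asns (chromosome 6, 7675169 to 7693254), asparagine synthetase and a target of ATF4, had 4.33 ± 9.51 and 0.717 ± 1.03 CPM there (SD, n = 8 each), and 0.992 ± 1.32 CPM in the controls without replicate 3 (SD, n = 7), which had 27.7. Cdkn1a (chromosome 17, 29090976 to 29100727), a cell cycle inhibitor, was at 22.7 ± 41.3 CPM in 24-month controls and 2.21 ± 2.71 CPM in 6-month controls (SD, n = 8 each), and at 8.27 ± 7.04 CPM in 24-month controls without replicate 5 (SD, n = 7). Igf1 (chromosome 10, 87858265 to 87937042), the growth factor under growth hormone control, had 979 ± 285 CPM, Cyp7a1 (chromosome 4, 6265612 to 6275633), the rate-limiting enzyme of bile acid synthesis, 304 ± 115 CPM, and Ppargc1a (chromosome 5, 51454250 to 51567726), a coactivator of mitochondrial and fasting genes, 49.8 ± 11.2 CPM in 6-month controls (SD, n = 8 each). Positions are those of GRCm38.

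What does restriction of all amino acids do in young males? On Low Amino Acid at 6 months 948 genes were higher and 1954 lower in the authors' deposited table. The authors' deposited table put Muc4, a mucin gene, up by 3.98 (adjusted p = 3.52e-05) on the log2 scale. Ppargc1a rose by 1.29 (adjusted p = 0.0027) in the authors' deposited table. RNAs without a usual poly(A) tail led the fall there: Rpph1, the RNA of RNase P, by -4.25 (adjusted p = 5.02e-05) and Rprl3 by -3.81 (adjusted p = 0.0013) in the authors' deposited table. Hist2h2aa2, at -6.23, and Ubtfl1, AI507597 and Pagr1b, at 5.32, 4.98 and 3.96, belong to families of near-identical copies and are uncertain in the authors' deposited table. Fgf21, Asns, Srebf1 and Cdkn1a did not pass there, with adjusted p = 0.202, 0.267, 0.781 and 0.487 in the authors' deposited table.

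Of 75 nuclear genes of oxidative phosphorylation 0 rose and 22 fell in young males on Low Amino Acid in the authors' deposited table (24 fell adjusted over the list alone), among them Uqcrq at -1.85 and Uqcr11 at -1.47. Fold changes of protein-coding genes in young males correlated with exon length, at a Spearman value of 0.185 on Low Amino Acid and 0.248 on Low Isoleucine, so shorter genes tended to be lower, and lists of short genes were not tested apart from this. The list had adjusted p = 0.984 with an estimated correlation. Of 78 genes of cytosolic ribosomal proteins 18 rose and 18 fell in the authors' deposited table (24 and 26 adjusted over the list alone), with Rpl36 at -2.11, Rplp1 at -1.96 and Rps24 at 0.48, a median of 0.0120 and a mean of -0.10, which differ in sign, and adjusted p = 0.984 with an estimated correlation. Of 36 genes of the integrated stress response 3 rose and 10 fell in the authors' deposited table (3 and 10 adjusted over the list alone), with Shmt2 at -0.79, Eif4ebp1 at -0.48 and Aars at -0.28. Endothelial markers had 0 of 24 up and 7 down in the authors' deposited table (7 down adjusted over the list alone), with Tie1 at -0.94 and Egfl7 at -0.69. Male-biased liver genes had 0 of 24 up and 5 down in the authors' deposited table (9 down adjusted over the list alone), led by Cyp4a12b at -2.61. No list call in any male comparison held with an estimated correlation, where the smallest adjusted p at 6 months on Low Amino Acid was 0.984.

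Restriction of isoleucine alone was the question of the next comparison, and in young males it went with 1661 genes higher and 2086 lower in the authors' deposited table. How many of the 7 libraries of this group entered that table is unknown, and it may be fewer than 7. Srebf1 fell by 1.57 on the log2 scale (adjusted p = 5.79e-04), while Cdkn1a stood at 3.31 (adjusted p = 0.0182) and Ppargc1a at 1.26 (adjusted p = 0.008) in the authors' deposited table. Fasn did not pass (adjusted p = 0.592 in the authors' deposited table). Of 24 male-biased liver genes 0 rose and 11 fell in the authors' deposited table (12 fell adjusted over the list alone), with Cyp4a12b at -3.19 and C6 at -1.50, and adjusted p = 0.499 with an estimated correlation. Of 23 female-biased genes 5 rose and 0 fell in the authors' deposited table (5 rose adjusted over the list alone), with Cyp17a1 at 2.69, Atp6v0d2 at 2.66 and Cyp2b9 at 6.09 (adjusted p = 0.0287). Interferon response genes had 0 of 31 up and 7 down in the authors' deposited table (10 down adjusted over the list alone), with Irf7 at -2.58 and Oas1a at -2.55, and adjusted p = 0.987 with an estimated correlation. Oxidative phosphorylation genes had 0 of 75 up and 23 down in the authors' deposited table (25 down adjusted over the list alone), and fibrosis genes 0 of 33 up and 11 down (13 down adjusted over the list alone) with Col4a2 at -0.99. These and the female-biased list had adjusted p = 0.987 with an estimated correlation. Of 13 mitochondrially encoded genes 9 rose and 1 fell in the authors' deposited table (11 and 1 adjusted over the list alone), with mt-Nd5 at 1.05 and mt-Cytb at 0.75, and no correlation could be estimated for them.

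Few genes passed the threshold in old males on either diet, though 2268 on Low Amino Acid and 2269 on Low Isoleucine had an unadjusted p under 0.05 in the authors' deposited table. Across genes, Low Isoleucine effects of 24-month males correlated at r = 0.449 with those of 24-month females and at 0.119 with those of 6-month males. On Low Amino Acid those values were -0.0512 and 0.0763. On Low Amino Acid 7 genes rose and 3 fell in the authors' deposited table, with Sorcs2 at 3.35 (adjusted p = 0.0015), Igf2bp2, an RNA-binding protein, at 1.07, Ctps2, a CTP synthase, at 0.95 and Usp36 at -0.47. The other genes that fell, Gm15883 and Gm17213, are named after their values were seen. On Low Isoleucine 7 rose and 5 fell in the authors' deposited table: the mitochondrial ribosomal RNAs mt-Rnr1 at 1.33 and mt-Rnr2 at 1.01, Palmd at 0.71, and Wfdc2 at -1.97, Slc10a2, a bile acid carrier, at -1.85 and Chrm3 at -1.63. Ppp1r7, at -0.33, and Gm47405, named after its values were seen, also fell in the authors' deposited table. Genes of fatty acid oxidation and ketogenesis had 0 of 26 past the threshold over all genes in 24-month males on Low Isoleucine and 19 up adjusted over the list alone in the authors' deposited table, with Acadl at 0.54 (adjusted p = 0.107). The list had adjusted p = 0.292 with an estimated correlation. Kupffer cell and macrophage markers had 0 of 26 past the threshold and 15 down adjusted over the list alone in the authors' deposited table, with C1qb at -1.30 (adjusted p = 0.147), and adjusted p = 0.627 with an estimated correlation.

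**Figure D2:**
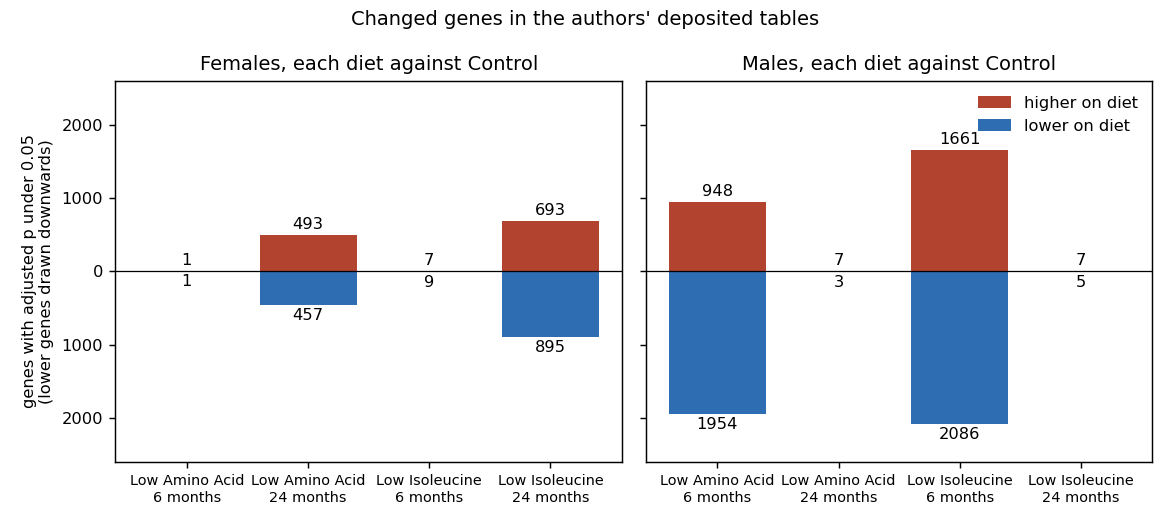
Genes higher and lower on each diet in the authors' deposited tables at an adjusted p under 0.05, by sex and age. Low Isoleucine in 6-month males had the most, 1661 higher and 2086 lower, and Low Amino Acid in 24-month males the fewest of the male comparisons, 7 and 3.

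Young females were compared from their counts. On Low Isoleucine 2 of 12623 genes passed with edgeR, against 39 with DESeq2, 63 with voom and quality weights, 23 with libraries of the same age alone and 91 without the libraries that stand apart. The 2 were both lower: Esr1, the estrogen receptor, by -0.84 (SE 0.1503, adjusted p = 0.0151) and Cd207, a marker of Langerhans and some dendritic cells, by -1.71 (SE 0.324, adjusted p = 0.0233). Cd207 lost the threshold for 7 of 47 libraries left out in turn. Replicate 3 of this diet group, labelled female, had Kdm5d, a gene of the Y chromosome, at 47.9 CPM against 0.490 in the next, and without it 3 genes passed. Esr1 stood at 91.3 ± 14.8 CPM in controls and 50.9 ± 7.98 CPM on the diet (SD, n = 8 each). Srebf1 was at -1.02 (SE 0.248, adjusted p = 0.146) and Fasn at -0.76 (SE 0.237, adjusted p = 0.208). On Low Amino Acid 0 genes passed with edgeR, 974 had an unadjusted p under 0.05, and DESeq2 gave 7. In the authors' deposited table of females 7 genes rose and 9 fell on Low Isoleucine, with Lhx6 at 0.88, Gstm2 at 0.86, Srebf1 at -1.15 and Esr1 at -0.81. On Low Amino Acid 1 rose and 1 fell in the authors' deposited table, Lhx6 at 0.96 and Gm22486, the second named after its values were seen.

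Old females on Low Amino Acid had 47 genes higher and 32 lower with edgeR. Slc34a2, a phosphate carrier, rose by 2.80 (SE 0.519, adjusted p = 0.0095), from 0.633 ± 0.481 CPM in controls (SD, n = 8) to 4.49 ± 1.66 on the diet (SD, n = 7). Apoa4, an apolipoprotein, rose by 1.36 (SE 0.299, adjusted p = 0.0244), while Inhbb, a subunit of activin, was at -2.08 (SE 0.429, adjusted p = 0.0181) and Cyp2c70, an enzyme of bile acid hydroxylation, at -1.26 (SE 0.255, adjusted p = 0.0181). Of 36 genes of the integrated stress response 0 rose and 2 fell (11 fell adjusted over the list alone), Atf4, its transcription factor, by -0.64 (SE 0.125, adjusted p = 0.0147) and Nars by -0.46 (SE 0.111, adjusted p = 0.0366), which lost the threshold for 8 of 47 libraries left out in turn. The list had adjusted p = 0.686 with an estimated correlation. The fit pooled the spread of all 6 female groups, and a fit on the 15 libraries compared called 1 gene. In the authors' deposited table, which leaves out 2 libraries of this diet group, 493 genes rose and 457 fell, with Slc34a2 at 2.91 and S100a8, a neutrophil gene, at -3.85. The 2 libraries it leaves out were those high in neutrophil genes, with list means of 4.28 and 3.63 in log2 CPM against at most -0.62 in the other 5. Aged control replicates 1 and 4, at 4.63 and 4.83, were not left out, and the other aged controls stood at 2.06 or less. No aged control is left out of that table, so part of the S100a8 fall there may follow from this choice of libraries.

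Old females on Low Isoleucine had 317 genes higher and 462 lower with edgeR, and genes of lipid synthesis and inflammation were among the lower ones. Of 24 acute phase genes 0 rose and 14 fell (21 fell adjusted over the list alone), with Fga, a fibrinogen chain, at -1.39 (SE 0.301, adjusted p = 0.0039) and Saa2 at -6.23 (SE 1.39, adjusted p = 0.0052), and adjusted p = 0.584 with an estimated correlation. Of 20 genes of fatty acid synthesis 0 rose and 5 fell (1 and 8 adjusted over the list alone), with Thrsp, a regulator of lipogenesis, at -3.28 (SE 0.620, adjusted p = 0.0012) and Fasn at -0.86 (SE 0.237, adjusted p = 0.0234). That list and the next 3 had adjusted p = 0.584 with an estimated correlation. Of 23 genes of cholesterol synthesis 0 rose and 6 fell (16 fell adjusted over the list alone), among them Nsdhl, a sterol dehydrogenase, at -1.24. Of 36 stress response genes 2 rose and 8 fell (2 and 11 adjusted over the list alone), with Chac1 at -2.82 (SE 0.592, adjusted p = 0.0032) and Asns at -2.80 (SE 0.856, adjusted p = 0.0404). Asns rests on control replicate 3, at 27.7 CPM with 3.91 in the next, and stood at -0.67 without it (adjusted p = 0.626). Fga stood at -0.74 at the least with a library left out, and Nsdhl lost the threshold for 10 of 47. Of 15 neutrophil genes 0 rose and 3 fell (11 fell adjusted over the list alone), with S100a8 at -3.66 (SE 0.922, adjusted p = 0.0123) from 32.9 ± 49.9 CPM in controls to 2.91 ± 4.56 (SD, n = 8 each). S100a8 ran from -4.65 to -2.96 with a library left out. In the diet group replicate 5 had a neutrophil list mean of 3.34 in log2 CPM, others -1.75 to 0.13. Among aged controls replicates 1 and 4 had 4.63 and 4.83, and the others 2.06 or less. Control replicates 2 and 6 lay within the -1.75 to 0.13 of the diet group. The fall of S100a8 was not tested without both control replicates 1 and 4. Cyp4a14, a fatty acid hydroxylase, rose by 1.72 (SE 0.410, adjusted p = 0.0089). A fit on the 16 libraries compared called 40 genes, and the diet group holds the library of 7.82 M counts.

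**Figure D3:**
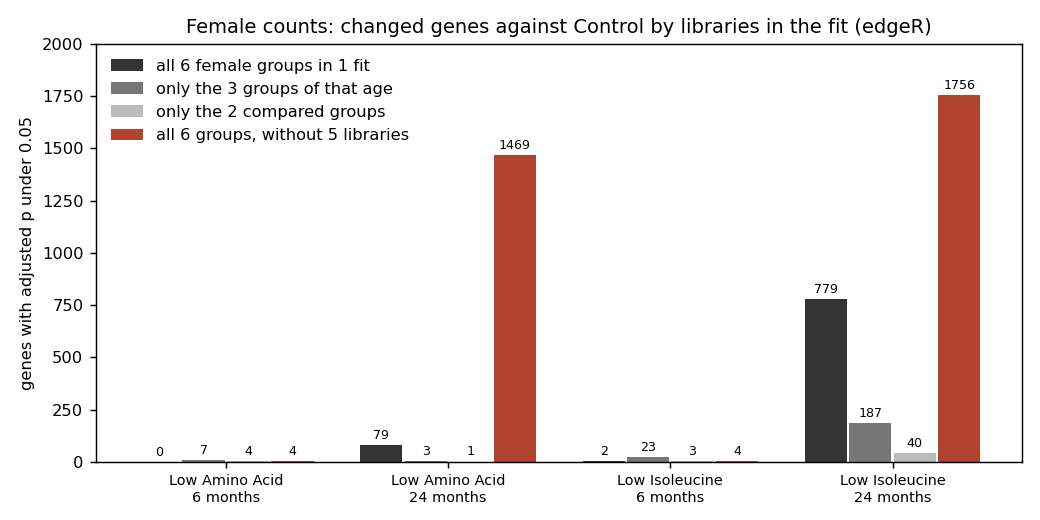
Bars give the number of genes with an adjusted p under 0.05 on each diet against Control in females, by the libraries in the edgeR fit. Low Amino Acid at 24 months went from 79 genes in the fit of 6 groups to 1 with the compared groups alone, and Low Isoleucine from 779 to 40.

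How far apart were the restricted diets? The answer from female counts depends on the fit. At 6 months 2 genes differed with edgeR on all 6 groups, 171 with libraries of the same age alone, 1.1e+02 (rounded to 2 digits) with the compared groups alone and 132 with voom and quality weights. The 2 genes were both lower on Low Isoleucine than on Low Amino Acid: Cd207 by -2.03 (SE 0.325, adjusted p = 0.0018) and Srebf1 by -1.34 (SE 0.249, adjusted p = 0.0175). At 24 months 134 genes differed, 26 of them higher on Low Isoleucine and the rest lower, with 16, 76 and 801 genes in those other fits and 45 to 210 with 1 library left out. Gadd45b, a stress gene, was at 1.34 (SE 0.343, adjusted p = 0.0404) and Cyp27a1, an enzyme of bile acid synthesis, at 0.63 (SE 0.141, adjusted p = 0.0183). Fabp5, a fatty acid carrier, was at -2.19 (SE 0.582, adjusted p = 0.049) and Bhlhe40, a clock repressor, at -0.98 (SE 0.221, adjusted p = 0.0191). With 1 library left out at a time, Fabp5 lost the threshold for 28 of 47 libraries and Gadd45b for 12. Across genes, the effects of the diets in females correlated at r = 0.400 at 6 months and 0.575 at 24 months, where simulated groups without change that share controls gave 0.501 and 0.478, so the 6-month value lies below it. With the controls split between the diets r was 0.0737 and 0.218. Genes are not independent replicates. At 24 months 17 genes rose and 15 fell on both diets, which share the 8 aged controls. Independent lists of these sizes give 1.18 and 1.17. With the controls split between the diets the medians were 4.50 and 4 (0 to 14 and 0 to 16 over 20 splits), where independent lists of the split sizes give medians of 0.89 and 2.85. Simulated unchanged groups with shared controls gave a median of 0 and 0. Groups without change leave few calls to overlap, so those values do not show what shared controls add to lists of these sizes.

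Averaged over both sexes and ages, 1863 genes were higher and 2182 lower on Low Isoleucine, computed from the deposited tables, and 2661 of these genes had the same sign in all 4 strata. Picking genes by the average of these same fold changes raises that last number, and its value without an effect was not computed. Across all genes, effects of single strata correlated at r = 0.0539 to 0.449. Srebf1 was at -0.99 (SE 0.141, adjusted p = 1.95e-05), Fasn at -0.56 (SE 0.134, adjusted p = 0.0029) and Thrsp at -1.53 (SE 0.345, adjusted p = 0.0018), computed from the deposited tables. G6pc2, a glucose phosphatase subunit, was at 1.71 (SE 0.238, adjusted p = 1.65e-05) and Pdk4, a brake on glucose oxidation, at 1.32 (SE 0.310, adjusted p = 0.0025), computed from the deposited tables. Of 31 interferon genes 0 rose and 23 fell (26 fell adjusted over the list alone), with Irf7 at -1.13 (SE 0.185), and adjusted p = 0.605 with an estimated correlation. Of 26 Kupffer cell and macrophage markers 0 rose and 18 fell (18 fell adjusted over the list alone), with C1qb, a complement subunit, at -1.02 (SE 0.189), and adjusted p = 0.797 with an estimated correlation. The female part of this average leaves out 24-month Low Isoleucine replicates 2 and 5, the highest of their group in macrophage markers (list means of 5.22 and 5.29 in log2 CPM, others 2.33 to 4.24), and replicate 2 was also the highest in interferon genes (5.36). Aged female control replicates 1, 4 and 7 stood at 5.43, 5.53 and 5.81 in macrophage markers (other aged controls 3.57 to 4.45) and were not left out. On the 11888 genes of the upper lines 3120 passed in this average from the deposited tables, and 2673 with females from all counts. Of 20 clock genes 3 rose and 12 fell (3 and 13 adjusted over the list alone), with Arntl at 1.35 (SE 0.292), and adjusted p = 0.605 with an estimated correlation. Of 20 fatty acid synthesis genes 0 rose and 8 fell (8 fell adjusted over the list alone), with a median of 0.0093 and a mean of -0.21, which differ in sign, and adjusted p = 0.823 with an estimated correlation.

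On Low Amino Acid the average had 974 genes higher and 1261 lower, computed from the deposited tables, with 1318 of the same sign in all 4 strata. Picking genes by their average raises this last number. Across genes, effects of single strata correlated at r = -0.0512 to 0.174. The female part leaves out 24-month Low Amino Acid replicates 2 and 4. Their list means of cytokine and chemokine genes were 3.22 and 3.39 in log2 CPM (others 1.17 to 1.53). Aged control replicates 1, 4 and 7, at 3.97, 3.04 and 3.84, were not left out. Lepr, the leptin receptor, was at 1.75 (SE 0.266, adjusted p = 1.81e-04), Slc34a2 at 1.90 (SE 0.379, adjusted p = 0.0015) and Mogat1, a triglyceride synthesis enzyme, at 1.15 (SE 0.310, adjusted p = 0.0132). Nnmt, a nicotinamide methyltransferase, was at -1.61 (SE 0.497, adjusted p = 0.0281) and Jun, an immediate early gene, at -0.99 (SE 0.256, adjusted p = 0.0095). Of 35 stress response genes 1 rose and 8 fell (1 and 9 adjusted over the list alone), with Aars at -0.29 (SE 0.0415) and Atf4 at -0.40 (SE 0.0594), and adjusted p = 0.884 with an estimated correlation. Of 19 immediate early genes 0 rose and 5 fell (6 fell adjusted over the list alone), with Junb at -0.98, and adjusted p = 0.884 with an estimated correlation. On the 11888 genes of the upper lines 1727 passed in this average from the deposited tables, and 1423 with females from all counts. Histone genes of this average, such as Hist2h2aa2 at -1.91, are uncertain for their near-identical copies.

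Tests of differences between sexes and ages called the most genes where 6-month males were compared. Each of those tests uses the 6-month male controls. Low Amino Acid effects differed between the ages in males for 1437 genes and in females for 6, computed from the deposited tables, and between the sexes at 6 months for 1377 genes and at 24 months for 24 (0 with females from counts). Ppargc1a stood at -1.40 for 24 minus 6 months in males (SE 0.440, adjusted p = 0.0412) and at -1.43 for females minus males at 6 months (SE 0.376, adjusted p = 0.0143). Averaged over the ages, the sexes differed for 3 genes (175 with females from counts), Grik5, a glutamate receptor subunit, at 1.06 (SE 0.201, adjusted p = 0.0355), Sulf2 at 1.05 (SE 0.188) and Irf2bp1 at 0.76. Averaged over the sexes, the ages differed for 3 gene models (0 with females from counts), Gm10800, Gm10801 and Gm26870, named after their values were seen. From female counts, 0 genes differed between the ages with edgeR on Low Amino Acid (1251 at an unadjusted p under 0.05, DESeq2 0, and 494 without the 5 libraries that the deposited table leaves out) and 0 on Low Isoleucine (1005, DESeq2 9). Low Isoleucine effects differed between the ages for 565 genes (422 on the genes of the upper lines, and 92 there with females from counts), for 1534 in males and 4 in females (Mcc, Bloc1s3, Pfn1 and, named after its values were seen, Gm22486), and between the sexes for 173 genes (661 with females from counts), 935 at 6 months and 1 at 24 months, Slc22a7, an organic anion carrier, at -3.18 (SE 0.566, adjusted p = 0.0377), and 0 with females from counts or on the genes of the upper lines. Genes of fatty acid oxidation had 7 of 26 with a higher Low Isoleucine effect at 24 than at 6 months and 0 lower (21 higher adjusted over the list alone), with Acot1 at 2.63 (SE 0.57, adjusted p = 0.0157) and adjusted p = 0.544 with an estimated correlation. Acute phase genes had 0 of 27 higher and 8 lower (16 lower adjusted over the list alone), with Fgg at -1.09 (SE 0.263, adjusted p = 0.0245) and adjusted p = 0.631 with an estimated correlation.

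What did ageing change on the Control diet? In females 2061 genes rose and 1392 fell from 6 to 24 months with edgeR, and a fit on the 16 control libraries alone called 2126 genes. Of 15 neutrophil genes 14 rose and 0 fell (14 rose adjusted over the list alone), with S100a8 at 5.52 (SE 1.03), and adjusted p = 0.403 with an estimated correlation. Of 25 Kupffer cell and macrophage markers 20 rose and 1 fell (23 and 1 adjusted over the list alone), with Ccr2 at 1.87, and adjusted p = 0.414 with an estimated correlation. B cell markers had 13 of 14 up and 0 down (14 up adjusted over the list alone), and adjusted p = 0.403 with an estimated correlation. Of 24 acute phase genes 19 rose and 0 fell (21 rose adjusted over the list alone), with Fga at 1.85 (SE 0.305, adjusted p = 7.89e-05), and adjusted p = 0.296 with an estimated correlation. Of 23 genes of fatty acid oxidation 0 rose and 14 fell (17 fell adjusted over the list alone), with Ehhadh at -1.23 and Ppara, their transcription factor, at -0.64, and of 24 genes of branched-chain amino acid catabolism 0 rose and 14 fell (18 fell adjusted over the list alone), with Hibch at -0.72. Both lists had adjusted p = 0.296 with an estimated correlation. Cdkn1a rose by 3.33 (SE 0.761, adjusted p = 0.0014), Lcn2, an acute phase gene, by 6.29 (SE 1.18, adjusted p = 3.05e-04), and Ppargc1a was at -0.77 (SE 0.226, adjusted p = 0.0099). Single libraries weigh on these values, since Cdkn1a stood at 124 CPM in replicate 5 of the aged controls and at 19.9 CPM in the next highest. Without that replicate Cdkn1a was at 1.89 (adjusted p = 0.0273). Fga stood at 1.20 at the least with a library left out.

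Male controls had 1480 genes higher and 2071 lower at 24 months in the authors' deposited table. Acute phase genes had 12 of 27 up and 0 down in the authors' deposited table (17 up adjusted over the list alone), with Fgb at 1.28, and adjusted p = 0.699 with an estimated correlation. Male-biased genes had 0 of 24 up and 12 down in the authors' deposited table (14 down adjusted over the list alone), with Cyp2d9 at -1.13, and fatty acid oxidation genes 0 of 26 up and 13 down (19 down adjusted over the list alone) with Ehhadh at -1.78. These lists had adjusted p = 0.411 and 0.699 with an estimated correlation. Lcn2 was at 5.06 (adjusted p = 0.0084) and Cdkn1a at 2.74 (adjusted p = 0.0428) in the authors' deposited table. Between the sexes 399 genes rose and 521 fell in both, where chance gives 178 and 227. Age effects differed between females and males for 1274 genes, computed from the deposited tables, with Col1a1, a collagen chain, at 2.55 (SE 0.581, adjusted p = 0.0069) and Bhmt, an enzyme of methionine recycling, at -1.94 (SE 0.420, adjusted p = 0.005). The Mup genes, with Mup1 at -6.12 (SE 1.23, adjusted p = 0.0032), are near-identical copies and uncertain. The diet comparisons of 6-month males and the age comparison of males share the 6-month male controls. Genes that fell with age and were lower on the diet at 6 months numbered 955 for Low Amino Acid and 1003 for Low Isoleucine. Independent lists of these sizes give 232 and 248, and 3 and 4 genes rose with age and were lower on the diet. Shared controls alone can make such overlaps, so these diet effects cannot be told apart from a peculiarity of the young male controls.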

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

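Chosen only after the result was seen were the tests of low depth, of pairs of aged controls and of dividing cells, and the list of clustered histone genes. The test of pairs of aged controls replaced an earlier one that left out the 2 aged controls with the highest first component; it was changed after that earlier result had been seen, because it picked samples by an outcome. The prediction for non-coding RNAs was written before their median was computed, but after single members (Rpph1, Rprl3, Snora78) had been seen.

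Low Amino Acid in 24-month females gave 79 genes with all libraries and many more without the 2 libraries of that diet, replicates 2 and 4, that the deposited female table leaves out. Low depth of this pair was argued against by their totals of 24.5 and 23.5 M counts, with a median of 22.4 M over libraries. Leaving out the library with the lowest total, another of the 5 that the deposited table leaves out, gave 1.0e+02 genes (rounded to 2 digits), which speaks of that library alone. Which 2 libraries are left out mattered: of the 21 pairs of diet libraries, 1, this pair itself, gave a count as large as its 848, with 171 the highest other and 10.5 the median other. More immune cells in these 2 libraries may contribute: in 3 of 4 immune cell lists both lay above all others of their group, at 4.57 or more against 3.90 for macrophages, 3.63 against -0.62 for neutrophils, and 0.25 against 0.08 for T and NK cells, while B cells did not (0.61 against 1.62). The acute phase list means of the 2 libraries were 9.12 and 10.7 in log2 CPM (others of the group 7.84 to 8.90). Their means of cytokine and chemokine genes were 3.22 and 3.39 (others 1.17 to 1.53). These values go with inflammation in these animals, for which no prediction was written. Another illness stays open, untested. Aged control replicates 1 and 4, at 4.63 and 4.83 in neutrophil genes, were not left out of the deposited table.

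Low Isoleucine and age effects ran opposite across genes in 24-month females (r = -0.505). This r is close to the -0.496 of simulated groups without change that share controls, so it says little by itself. Shared aged controls alone were argued against by the splits: with the controls split between the comparisons the median over 20 splits was -0.268, below 0 in 20 of 20. The covariance was -0.101 against -0.0307 simulated, which cannot decide. The simulation drew each gene on its own with a spread pooled over all groups, while aged controls varied more than any other female group. A few aged control libraries could carry it: leaving out 5 of the 28 pairs of aged controls brought the value above -0.1, up to 0.0188. A diet effect against ageing stays open as a hypothesis.

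In 6-month males clustered histone genes and other RNAs without a poly(A) tail were lower on both diets: 19 of 29 histone genes fell on Low Amino Acid (median -2.09) and 19 of 29 on Low Isoleucine (median -2.05), and 0 of 29 in 24-month males. Fewer dividing cells were argued against, because the higher median of the proliferation list was 0.0728. Preparation or RNA state of the young male controls was set against the medians of non-coding RNAs, the higher of which was -0.297 (95% bootstrap interval -0.40 to -0.19), nearer 0 than the -0.50 set beforehand. That interval was drawn over the non-coding RNAs of a single comparison, not over animals. It holds no spread between animals or preparations, so it cannot decide on this explanation. In 6-month females the same RNAs had medians of -0.51 and -0.65, while 0 of 29 histone genes rose or fell there (medians 0.13 and -0.13), so at 6 months histone calls were seen in males alone. In 24-month females 0 of 29 passed on either diet, with medians of -0.48 and -0.27 and 26 and 23 of 29 below 0. The difference between the sexes was not tested for this list. In male controls 8 of the histone genes fell and 1 rose with age (median -0.45). Some difference in preparation or RNA state may remain. A bias by gene length was set against the correlation of fold change with exon length over all genes, the smaller of which was 0.0471. Histone genes are protein-coding, and among protein-coding genes the values were 0.185 and 0.248. The value over all genes therefore cannot decide, and a bias by length stays open. What else may lower these RNAs was not tested.

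A sample far from the others of its group was found in 11 of 66 tests, each of 1 measure in 1 of the 6 female groups, where chance gives about 1 in 20. Several fell in the same library. The total of 24-month Low Isoleucine replicate 5 was 7.82 M counts. Igf1 stood at 1780 CPM in 24-month control replicate 5, next 1165. Cdkn1a stood at 124 CPM in that same library, next 19.9. Ppargc1a stood at 67.5 CPM in 24-month Low Amino Acid replicate 2, next 42.1, and at 99.4 CPM in 6-month Low Isoleucine replicate 8, next 58.4. Asns stood at 27.7 CPM in 24-month control replicate 3, next 3.91, at 3.19 CPM in 24-month Low Isoleucine replicate 5, next 0.924, and at 1.11 CPM in 6-month control replicate 2, next 0.458. Fgf21 stood at 125.5 CPM in 24-month control replicate 3, next 60.4. Kdm5d, a gene of the Y chromosome, stood at 0.367 CPM in 6-month Low Amino Acid replicate 1, next 0.158, and at 47.9 CPM in 6-month Low Isoleucine replicate 3, next 0.490. In that last library, labelled female, female-biased genes had a median of -2.44 (18 genes) and male-biased genes 1.89 (14 genes), where the other 7 libraries of its group ran from -0.07 to 0.18 and from -0.43 to 0.76. These values go against the label. A test of its sex label was run with predictions written before it, which were afterwards withdrawn to keep to 3 weighed patterns, so its result stands here as values alone.

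Effects that differed between sexes or ages, by tests of the difference computed from the deposited tables, were counted as genes. For Low Amino Acid there were 3 between the sexes, 3 between the ages, 1437 between the ages in males, 6 in females, 1377 between the sexes at 6 months and 24 at 24 months. For Low Isoleucine there were 173 between the sexes, 565 between the ages, 1534 between the ages in males, 4 in females, 935 between the sexes at 6 months and 1 at 24 months. The age effect differed between the sexes for 1274. Ppargc1a differed on Low Amino Acid by -1.40 between the ages in males and by -1.43 between the sexes at 6 months. Lines of the gene table not used in any comparison, read as the female libraries in order, gave fold changes that correlated with the deposited female ones at r = 0.874 to 0.932 over 4 comparisons (5240 genes).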

How the results depend on the processing

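Chosen after seeing the data were the fits without the 5 libraries, without the lowest total, by limma-voom without weights, on the compared groups, on the same age, and with each library left out. In all, 7 planned settings and 5 added ones were run, and 47 with a library left out; of 1354 values of named genes in the first 12, 1183 kept their direction and side of the threshold, 162 lost the threshold, 7 gained it and 2 reversed. With 1 library left out, of 237 named values past the threshold 84 lost it for at least 1 library and 0 changed sign, while 25 of all 302 named values did. Saa3, lower on Low Isoleucine than on Low Amino Acid at 24 months (-3.25), turned to 0.0707 without the libraries that stand apart and 0.0778 without the 5. Both leave out Low Amino Acid replicate 4, without which alone Saa3 was at -0.007 (adjusted p = 0.998). Without the libraries that stand apart no aged control was left, so comparisons with them gave no value. The planned fit of all 92 libraries, and with it the settings for both sexes, was not run.

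Counts of changed genes in females moved as follows, and the cause was not tested. DESeq2 gave 7 on Low Amino Acid and 39 on Low Isoleucine at 6 months, 262 on Low Amino Acid at 24 months, 23 and 293 between the diets at 6 and 24 months, and 9 for the age difference on Low Isoleucine. Voom with quality weights gave 52, 63, 132 and 801 for Low Amino Acid at 6 months, Low Isoleucine at 6 months, and the diets at 6 and 24 months. Plain voom gave 1 for Low Isoleucine at 6 months. No filter gave 89 between the diets at 24 months. Without the libraries that stand apart the values were 7 and 91 at 6 months, and 132 and 396 between the diets. Without the 5 libraries they were 4 and 4 at 6 months, 1469 and 1756 at 24 months, 80 between the diets at 24 months and 494 for the age difference on Low Amino Acid. With only the compared groups they were 4 on Low Amino Acid at 6 months, 1 and 40 at 24 months, 1.1e+02 (rounded to 2 digits) and 76 between the diets, and 2126 for age. With only the same age they were 7 and 23 at 6 months, 3 and 187 at 24 months, and 171 and 16 between the diets.

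Title numbers shared within a group served as a replicate block, with a within-number correlation of 0.114; no number is in both groups of a comparison, so no pairing is possible. With the block 1 gene passed for Low Isoleucine at 6 months, as with plain voom, and against plain voom the block moved no count by over 1.5 times.

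On genes of the upper lines the averages gave 1727 (Low Amino Acid) and 3120 (Low Isoleucine) genes from the deposited tables, and the age difference on Low Isoleucine 422. With females from counts on those genes, averages gave 1423 and 2673, differences between the sexes 175 and 661, between the ages 0 and 92, and between the sexes at 24 months 0 and 0. On genes of the upper lines alone, Low Amino Acid gave 8 between the sexes, 0 between the ages and 1 between the sexes at 24 months, and Low Isoleucine 0 for the last. Camera with an estimated correlation called 0 lists in all 14 comparisons, and fry 0 in 7 of 9, 2 for Low Isoleucine at 24 months. Correlations of the diets fell to 0.0737 and 0.218 with controls split.

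Leaving out each library gave 0 to 7 (Low Amino Acid, 6 months), 0 to 4 (Low Isoleucine, 6 months), 15 to 244 and 486 to 956 (24 months), 1 to 6 and 45 to 210 (between the diets), 2630 to 3933 (age) and 0 to 0 (both age differences). For Low Amino Acid at 24 months, leaving out control replicates 1, 2, 4, 5, 6, 7 and 8 gave 15, 124, 157, 28, 147, 50 and 1.2e+02 (rounded to 2 digits), and diet replicates 1 to 7 gave 35, 133, 51, 244, 18, 19 and 27. For Low Isoleucine at 24 months, control replicate 1 gave 486 and diet replicate 1 gave 514. Between the diets at 24 months, control replicate 5 gave 210, Low Amino Acid replicates 1, 4, 5, 6 and 7 gave 82, 61, 59, 74 and 86, and Low Isoleucine replicates 1, 3, 4 and 8 gave 45, 80, 81 and 49. At 6 months, for Low Amino Acid control replicate 6 gave 7, 24-month control replicates 2 and 3 gave 5 and 3, and 24-month Low Amino Acid replicate 4 gave 3. For Low Isoleucine control replicate 8 gave 4 and diet replicates 1, 5, 6 and 7 gave 1, 0, 0 and 1. Between the diets control replicate 5 gave 4, 24-month control replicate 5 gave 6, Low Amino Acid replicates 3 and 5 gave 1 and 1, and Low Isoleucine replicates 2, 4 and 8 gave 1, 5 and 1.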

Other observations

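Chosen after the result was seen were the fits on the compared groups alone, used for the splits of the libraries, the simulated and split overlaps, and the counting of overlaps from the deposited tables, since the planned overlaps were of calls from counts.

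Genes changed by both diets were shared in young males: 487 rose and 1518 fell on both and 0 went opposite ways, counted from the authors' deposited table. In 24-month females 160 rose and 218 fell on both, counted from the authors' deposited table. Genes that rose with age in female controls and were lower on Low Isoleucine at 24 months numbered 559, counted from the authors' deposited table. Each of these pairs of comparisons shares control libraries, which alone can make genes overlap, and for the deposited tables no value without change was computed. From female counts 217 genes rose with age and were lower on Low Isoleucine at 24 months, where independent lists of these sizes give 75.4. With the aged controls split the median was 86.5 (31 to 130 over 20 splits), where independent lists of the split sizes give a median of 43.9. Simulated unchanged groups with shared controls gave a median of 0. Groups without change leave few calls to overlap, so that value does not show what shared controls add to lists of these sizes.

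In each comparison of female libraries 100 splits into groups of the same sizes were counted, the real one included. The splits moved single libraries, although some libraries of a group share a title number, so an effect of a shared number could not be excluded by them. By the share of splits, chance placing of single libraries was excluded for Low Amino Acid at 6 months, where 1 split gave a result as large (4 genes, highest other 1). The same held for Low Isoleucine at 6 months (1 split, 3 genes, highest other 2). These margins are of 1 to 3 genes, and the fit on all groups called 0 and 2 genes (0 to 7 and 0 to 4 with 1 library left out), so little rests on them. Between the diets chance placing of single libraries was excluded at 6 months (1 split, 1.1e+02 genes (rounded to 2 digits), highest other 1) and at 24 months (1 split, 76 genes, highest other 1). At 6 months the fit on all groups called 2 genes between the diets (1 to 6 with 1 library left out). For age in controls 1 split was as large (2126 genes, highest other 265). For Low Amino Acid at 24 months 2 of 100 splits gave as many as the real 1 gene, highest other 1. For Low Isoleucine at 24 months 2 of 100 gave as many as the real 40 genes, and the highest other, 872 genes, points to a structure of the samples other than diet. For the differences between ages the real count was 0, so 100 of 100 splits gave as many by construction and the splits decide nothing there. Their highest others were 23 and 517 on Low Amino Acid and Low Isoleucine.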
